A study of Mus musculus with 6 samples.

How the data were processed

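RNA from mouse stomach was sequenced by the authors in 6 libraries, 3 from mice given saline by gavage and 3 from mice given Riclin, a soluble dietary fibre, at 20 mg per kg for 14 days. Per the labels' protocols, total RNA was extracted with TRIzol, its integrity was read on a Bioanalyzer, and libraries were made with the VAHTS Universal V6 kit. Per the submitters' processing notes, the genome build was mm10 and Bowtie2 was used, with no role or version given. The counting tool, the gene annotation and the use of strand are not given in the sources used here.

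The authors deposited 1 table of FPKM values (fragments normalised to gene length and library size) for 23550 gene symbols in the 6 libraries. Groups come from the treatment label of each sample, and replicate numbers from the sample titles, so that the saline libraries carry the numbers 1, 2 and 4 and the Riclin libraries 2, 3 and 4. The labels do not say for each library that it came from a separate animal, so p-values measure only the spread between these libraries. Symbols were used as the table gives them, and 19635 of the 23550 were found in the annotation from which positions were taken (GENCODE M21 on GRCm38, the assembly that mm10 names).

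Because FPKM values are whole read numbers divided by gene length and library total, the reads behind them were recovered from the ratios between libraries. Whole reads were obtained for all 23550 genes, within a relative tolerance of 1e-09. On simulated libraries the same steps recovered exactly 98.2% of the 944 genes with at least 20 reads in every library. Of the 23550 genes here 13658 had that many, and the check does not cover the others. The library totals implied by the values lay between 30884067 and 40050267 reads, a range of 1.30-fold. The recovered reads were used for depth, for shares of reads with 95% Wilson intervals, which cover counting error only, and for 1 added alternative fit.

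Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, 11738 in all. Values were put on the scale log2(FPKM + 1), so that fold changes of genes with low values are understated. Riclin was compared with saline by limma (version 3.58.1, R 4.3.3) with an intensity trend in the variance prior, no covariate and two-sided tests, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. A wider set of genes with an unadjusted p under 0.05 and a change of at least 2-fold was counted to describe size and direction. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 43 of 45 lists with at least 5 tested members. The lists, fixed before the data were examined, cover the cell types of the stomach wall, tissues that a dissection could include, functions of the mucosa and signs of RNA quality. A panel of 44 mucosal barrier genes, of which 37 were tested, was adjusted over the panel alone as well as over all genes. Adjustment of the members of a gene list over that list alone was not part of the plan. On data simulated with the spread of these libraries, the fit on 11738 genes called 76 of 100 genes changed 2-fold and 97 of 100 changed 4-fold, with 6 unchanged genes called. The adjusted threshold is stricter where fewer genes change. These shares therefore hold for that many changed genes and do not give the power of the real comparison. With no change simulated the fit called 0 genes and 0 lists. Genes were simulated independently of one another, so this does not show how the list test behaves where members vary together. In these data the estimated inter-gene correlation was 0.65 for the interferon-stimulated list and 0.55 for the ribosomal list.

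The genes named in the text follow a rule fixed before the data were examined. It takes 8 genes in each direction, those past the adjusted threshold first and then those with the smallest unadjusted p among genes at least 2-fold different with no overlap between the groups. Symbols of predicted or unnamed genes, single immunoglobulin and T cell receptor segments and small RNA genes are left out of these 8, and 1 gene that the rule chose among the lower is not reported here. The rule adds up to 8 panel members with the smallest p, always Muc5ac, Muc6, Tff1, Tff2, Gkn1, Atp4a, Atp4b and Gast, and up to 4 members of each list past its test. Genes named outside it, among them Anpep, Alpi, Zg16, Reg3a and Clps, were chosen after their values were seen.

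Alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter at an FPKM of 5, median-of-ratios and upper-quartile scaling, a robust variance prior, the replicate number as a block, each library left out in turn, and a camera correlation estimated from the data. After the data were seen, limma's voom on recovered reads, fits that removed or adjusted for pancreatic transcripts, a fit without the libraries low in them, and limma's fry were added. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.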

Results

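Stomach RNA was compared between mice given Riclin and mice given saline, with 3 libraries in each group. Riclin is a soluble dietary fibre, a polysaccharide secreted by a bacterium. The comparison addresses how Riclin acts on the gastric mucosal defence barrier, the layer of mucus, epithelium and protective factors that shields the stomach wall from acid. The experiment held 20 mice, in a saline and a Riclin group. Ethanol was given in a separate experiment of the study, and whether the mice behind the 6 libraries received it is not given in the sources used here. The FPKM values imply totals of 38872411, 36022386 and 30884067 reads for saline replicates 1, 2 and 4, and of 37253728, 40050267 and 38022658 reads for Riclin replicates 2, 3 and 4.

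No single gene passed the adjusted threshold, and Clca1, lower in the Riclin stomachs, had the smallest p. Interferon-stimulated genes were higher as a list at the preset correlation (32 of 36 members, camera adjusted p = 1.56e-11, and adjusted p = 0.724 with an estimated correlation). Bst2, an interferon-induced membrane protein that tethers budding virus particles, measured 53.6 ± 4.44 FPKM in saline and 149 ± 40.9 in Riclin (SD, n = 3 each), 2.78-fold higher. Irf7, a transcription factor of the type I interferon response, measured 38.0 ± 6.62 and 102 ± 23.5 FPKM, 2.70-fold higher. Clca1, a secreted protein of mucus-producing cells, measured 343 ± 35.2 FPKM in saline and 103 ± 22.9 in Riclin, 3.32-fold lower. In these 3 genes every Riclin library lay on one side of every saline library. On GRCm38, Bst2 lies on chromosome 8 from 71534255 to 71537456, Irf7 on chromosome 7 from 141262706 to 141266481 and Clca1 on chromosome 3 from 145003817 to 145032776, all protein-coding and on the minus strand.

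By limma, 0 of 11738 genes passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.156, for Clca1 (log2 fold change -1.74, SE 0.195). An unadjusted p under 0.05 was found for 693 genes, 478 higher and 215 lower in Riclin. The average expected with no difference is 587. Other splits of the 6 libraries gave 223 to 1054 such genes, so the real count does not stand out. Over all genes the median log2 fold change was 0.040, and -8.5e-04 with median-of-ratios scaling, so the lean to higher genes may depend on scaling. Limma's voom on recovered reads also called 0 genes. The groups did not overlap in 1310 genes, 11.2% of those tested, where chance gives 10%. A change of at least 2-fold with an unadjusted p under 0.05 was seen in 50 genes, 24 higher and 26 lower. That count was 137 without saline replicate 2, and its split was 12 higher to 29 lower with median-of-ratios scaling and 12 to 28 with upper-quartile scaling. Clca1 passed the adjusted threshold with a robust variance prior (limma adjusted p = 0.0314) and, with Irf7 and Pcp4, after pancreatic genes were removed and the libraries rescaled (limma adjusted p = 0.0446 for each). Over 17 alternatives the limma adjusted p ranged from 0.0314 to 0.648 for Clca1, from 0.0446 to 0.762 for Irf7 and from 0.0446 to 0.648 for Pcp4, and the log2 fold change of Clca1 from -1.85 to -1.55.

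Of the other genes that the rule named as higher in Riclin, none of them past the adjusted threshold, 3 are also interferon-stimulated. Ifi44 measured 2.78 ± 0.308 and 9.34 ± 4.11 FPKM (SD, n = 3 each). The RNA sensor Ddx58 was 2.28-fold higher in mean FPKM. Oas2, which makes the activator of an antiviral ribonuclease, measured 17.4 ± 3.21 and 36.7 ± 10.4 FPKM. B4galnt3, a glycosyltransferase that adds N-acetylgalactosamine to glycans, was 2.12-fold higher in mean FPKM. Cd177, a surface protein of neutrophils, was 3.05-fold higher at a Riclin mean of 3.04 FPKM. H2-T24, a class I-like gene of a family whose members share sequence, was 2.53-fold higher, and its reads may be split among relatives.

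On the lower side, Pcp4, a small calmodulin regulator, measured 18.6 ± 2.09 FPKM in saline and 8.67 ± 1.56 in Riclin (SD, n = 3 each). B3galt5, a galactosyltransferase of glycan chains, was 2.78-fold lower. Jchain, which joins the units of secreted IgA and IgM, measured 15.4 ± 4.89 and 6.21 ± 1.92 FPKM. Cd3g, a T cell receptor subunit, measured 2.92 ± 1.46 and 0.527 ± 0.191 FPKM. Omp and Atcayos had saline means of 2.04 and 1.97 FPKM and Riclin means under 1 FPKM. Atcayos is annotated as antisense, and without strand its reads cannot be told from those of its partner gene.

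**Figure D1:**
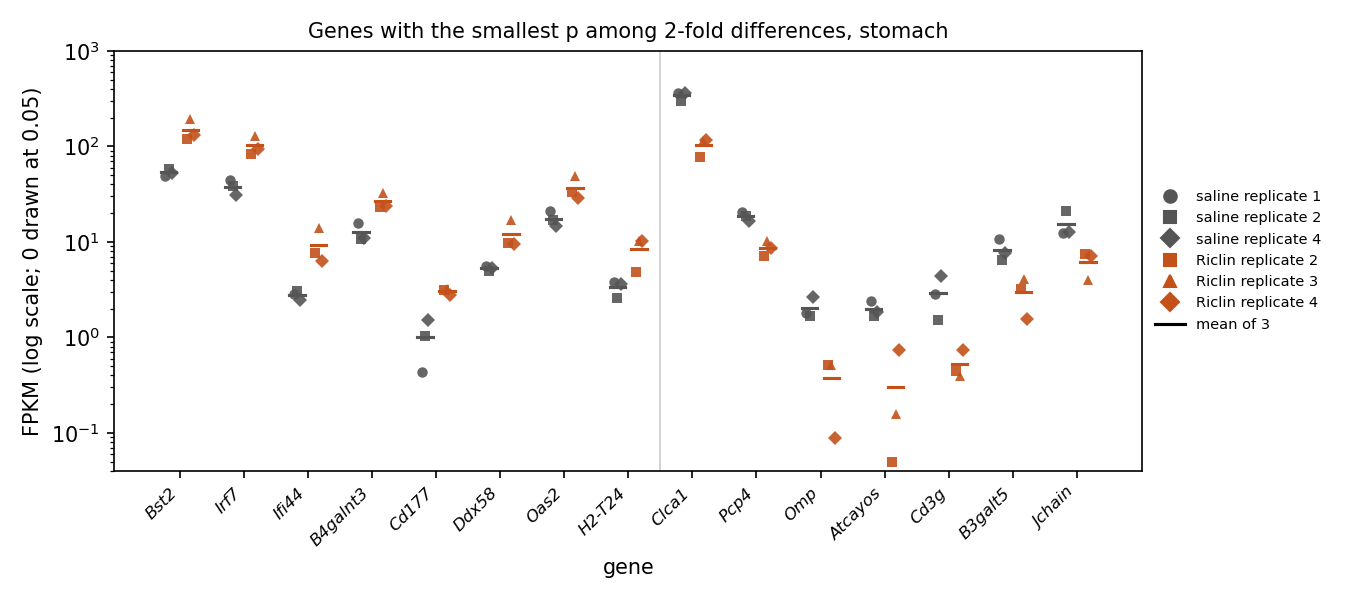
FPKM on a log scale of the 15 genes named by rank, 8 higher and 7 lower in Riclin, with 1 point per library (grey for saline, orange for Riclin, shape for the replicate number) and a bar for the mean of 3. In each gene the Riclin points lie on one side of the saline points, as for Clca1 with 303 to 365 FPKM in saline and 77.0 to 118 in Riclin.

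Interferon-stimulated genes were higher as a group in Riclin (camera adjusted p = 1.56e-11 at the preset correlation, and adjusted p = 0.724 with an estimated correlation). Of 36 tested members 32 were higher and 4 lower, with a median log2 fold change of 0.69. Adjusted over the list alone, 17 members passed by limma, and over all genes 0 did. In 17 members the groups did not overlap, each with Riclin higher. Riclin replicate 3, the library with few pancreatic transcripts, stood highest, and without it the median was 0.33. The median was 0.34 with the replicate block, which takes that library out of the comparison as well. The list's mean log2 level was 3.60 ± 0.08 in saline and 4.19 ± 0.53 in Riclin (SD, n = 3 each), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. The list also passed camera in 6 of the 9 other splits of the 6 libraries, with an adjusted p down to 1.92e-09.

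Panel genes of the mucosal barrier did not differ past the threshold: 0 of 37 passed by limma over all genes, and 0 adjusted over the list alone, where the smallest adjusted p was 0.302. The main gel-forming mucin of the surface, Muc5ac, measured 405 ± 122 FPKM in saline and 372 ± 132 in Riclin (SD, n = 3 each), and Muc6, the mucin of the gland base, 41.7 ± 10.9 and 32.8 ± 8.55 FPKM. The surface peptides Tff1 and Gkn1 had log2 fold changes of -0.15 (SE 0.488) and -0.22 (SE 0.408). Their relatives made deeper in the glands had lower means in Riclin, Tff2 at 6989 ± 3846 and 3479 ± 1789 FPKM and Gkn3 at 1155 ± 705 and 452 ± 206 FPKM. Their log2 fold changes of -1.003 (SE 0.509) and -1.28 (SE 0.447) were -0.58 and -0.82 without saline replicate 4, and that of Tff2 was -0.63 without Riclin replicate 4. The direction for Muc5ac and Tff1 turned when saline replicate 1 or Riclin replicate 4 was left out. Of the protective enzymes and factors, Sod2, a mitochondrial superoxide dismutase, was 1.22-fold higher, Vegfa 1.17-fold higher and the chaperone Hspa1b 2.25-fold higher in mean FPKM, while the prostaglandin receptor Ptger4 was 1.36-fold lower. None of these passed either adjustment. For Hspa1b the groups overlapped, and its log2 fold change of 1.03 was 0.59 without Riclin replicate 3.

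Acid-secreting parietal cell genes were higher in Riclin at the preset correlation (16 of 17 members, median log2 fold change 0.28, camera adjusted p = 3.68e-05), with an adjusted p of 0.724 with an estimated correlation. The median was 0.17 without saline replicate 4. The potassium channel genes Kcnj16 and Kcnq1 were 1.39-fold and 1.30-fold higher, the nuclear receptor Esrrg 1.35-fold and the water channel Aqp4 1.25-fold. The proton pump subunits Atp4a and Atp4b had log2 fold changes of 0.42 (SE 0.238) and 0.34 (SE 0.271). Cblif, the vitamin B12 carrier made by chief cells in mice, measured 1226 ± 326 FPKM in saline and 1845 ± 173 in Riclin (SD, n = 3 each). Somatostatin (Sst) was 1.38-fold higher and the histamine-forming enzyme Hdc 1.27-fold higher. The antral hormone gastrin (Gast) measured 885 ± 187 and 271 ± 233 FPKM, with 420, 389 and 2.62 FPKM in Riclin replicates 2, 3 and 4, and its log2 fold change of -3.37 was -1.11 without Riclin replicate 4. The antral transcription factor Pdx1, chosen after its values were seen, also lay lower in each Riclin library, at 3.85, 4.29 and 1.93 FPKM against 6.51, 7.16 and 8.48 in saline.

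Surface mucous and mucous neck cell genes were lower at the preset correlation (medians -0.15 over 12 members and -0.33 over 6, camera adjusted p = 0.0422 and 0.00362). With an estimated correlation the adjusted p was 0.784 for the surface list and 0.724 for the neck list. Krt20, a keratin of mature surface cells, measured 223 ± 44.5 and 126 ± 61.0 FPKM (SD, n = 3 each). The proteases Capn8 and Capn9 and the mucin-like Mucl3 had log2 fold changes of -0.57, -0.15 and -0.31, and that of the small membrane protein Smim6 was -0.19, and Capn9 turned without saline replicate 1. Capn8 was at -0.24 without saline replicate 4 and Mucl3 at -0.043 without Riclin replicate 4. Riclin replicate 4, lowest in Gast, was also lowest in Krt20, at 60.2 FPKM. Without saline replicate 1 the surface median was 0.06 and the list did not pass (camera adjusted p = 0.524), and without Riclin replicate 4 it was -0.014 and did not pass either (0.205). That median was -0.26 without saline replicate 4 and -0.27 without Riclin replicate 3. The call was also lost under 6 further settings (camera adjusted p from 0.0589 to 0.329). The median stayed at -0.15 with no filter, -0.20 and -0.19 with median-of-ratios and upper-quartile scaling, and -0.20 with pancreatic genes removed. It was -0.071 both with the replicate block and with both low-pancreas libraries left out. The neck median was -0.17 without Riclin replicate 2, -0.20 without saline replicate 4, -0.50 without saline replicate 1 and -0.53 without Riclin replicate 4.

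Genes listed for intestinal absorptive and goblet cells were lower (10 of 14 members, median log2 fold change -0.72, camera adjusted p = 0.00265, and adjusted p = 0.724 with an estimated correlation). Of the lower members, Zg16 is also in the acinar list, at 40.2 FPKM in Riclin replicate 3 and 1232 to 4677 in the other libraries. Reg3a was 0 FPKM in Riclin replicate 3 and 117 to 1050 in the others. Both were picked after their values were seen. By limma 2 members passed adjusted over the list alone and 0 over all genes: Clca1, lower, and the brush border peptidase Anpep, higher at 60.2 ± 8.87 FPKM in Riclin against 38.3 ± 5.99 in saline (SD, n = 3 each, limma adjusted p over the list = 0.0255). Anpep lies outside the naming rule and was named after its values were seen. The retinol carrier Rbp2 was 1.70-fold lower and the fatty acid carrier Fabp2 2.72-fold lower. The mucus protein Fcgbp was 3.82-fold lower, with 0.630 FPKM in Riclin replicate 4 beside a Gast level of 2.62 FPKM there. The median was -0.21 without Riclin replicate 3 (camera adjusted p = 0.0519), and the list did not pass without saline replicate 4 (median -0.63, 0.0662). Saline replicate 4 had the highest level of the intestinal enzyme gene Alpi, 42.0 FPKM against 0.146 to 1.998 in the other libraries. The call was also lost with median-of-ratios scaling (median -0.77, camera adjusted p = 0.0584) and with pancreatic genes removed (-0.74, 0.0765). With the pancreatic score as a covariate it was lost at a smaller median (-0.17, 0.0722).

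Squamous genes of the forestomach, the keratinised part of the mouse stomach, were higher (34 of 39 members, median log2 fold change 0.75, camera adjusted p = 5.76e-07, and adjusted p = 0.724 with an estimated correlation). The keratins Krt17, Krt6a and Krt14 were 1.68-fold, 1.66-fold and 1.93-fold higher, and the cornified envelope protein Rptn 2.17-fold. Saline replicate 1 was lowest in this list, and without it the median was 0.27 (camera adjusted p = 0.173). The median was 1.20 without saline replicate 2. Without the 2 libraries low in pancreatic transcripts it was 0.23, and the list did not pass (camera adjusted p = 0.12). With the replicate block the median was 0.23 as well, by construction. The list kept its call there, but on the same remaining libraries, so this is no further check. The list took 0.208 ± 0.0859% of reads in saline and 0.291 ± 0.0393% in Riclin (SD, n = 3 each).

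Pancreatic acinar genes were lower (27 of 28 members, median log2 fold change -3.003, camera adjusted p = 1.40e-08, and adjusted p = 0.724 with an estimated correlation). Clps, the member that was not lower, stayed at 23892 to 46052 FPKM in all 6 libraries. It was highest in Riclin replicate 3 and so did not follow the other members. Without Clps the acinar genes took 4.46, 18.1 and 16.8% of reads in saline replicates 1, 2 and 4, and 12.4, 0.0640 and 11.6% in Riclin replicates 2, 3 and 4. The 95% Wilson interval for Riclin replicate 3 was 0.0632 to 0.0648%. In that library the trypsin inhibitor Spink1 was listed at 0 FPKM, the amylase Amy2b at 0.230, the zymogen granule protein Sycn at 8.20 and the trypsinogen Try5 at 0.655, and Spink1 measured 143 to 516 FPKM in the other 5. Without Riclin replicate 3 the median was 0.11 and the list did not pass (camera adjusted p = 0.438). With saline replicate 1, the next lowest library, left out too, the median was -0.53 and the list passed (camera adjusted p = 3.66e-14). The replicate block compares the same remaining libraries, so its equal median is no further check (camera adjusted p = 5.41e-15). Without Riclin replicate 4 the median was -4.65. With the pancreatic score as a covariate the list did not pass (camera adjusted p = 0.653). That score is the mean of these same genes, so it takes out their difference by construction and tests nothing here. The first principal component, 55.1% of the variance, set Riclin replicate 3 apart from the rest.

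Heat shock genes were higher (19 of 19 members, median log2 fold change 0.29, camera adjusted p = 9.69e-05), as were genes of protein folding in the endoplasmic reticulum (25 of 27, median 0.11, camera adjusted p = 0.00581). With an estimated correlation the adjusted p was 0.724 for both lists. The chaperones Hspa8, Hsph1, Dnaja1 and Dnajb1 were 1.32-fold, 1.67-fold, 1.44-fold and 1.46-fold higher. In the folding list, the degradation factors Herpud1 and Syvn1 were 1.46-fold and 1.32-fold higher, the chaperone Hyou1 1.20-fold and the stress transcription factor Ddit3 1.39-fold. Without saline replicate 1 neither passed, though the medians stayed at 0.26 and 0.10 (camera adjusted p = 0.0701 and 0.403). Riclin replicate 3, the library with few pancreatic transcripts, was highest in both. Without that library the medians were 0.16 and 0.063. Neither list passed with the replicate block (camera adjusted p = 0.423 and 0.394) or without the 2 libraries low in pancreatic transcripts (0.417 and 0.398). The medians were 0.12 and 0.055 in each, the same by construction. The folding median was also 0.063 with median-of-ratios scaling.

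Cytosolic ribosomal protein genes were lower (80 of 83 members, median log2 fold change -0.19, camera adjusted p = 2.22e-15, and adjusted p = 0.724 with an estimated correlation), with a median of -0.12 without saline replicate 2. Rps26, Rpl30, Rpl36a and Rpl23 had log2 fold changes of -0.93, -0.94, -0.30 and -0.27. These genes have many processed pseudogenes, and how reads shared with them were counted is not given, so their values are uncertain. Rpl21, chosen after its values were seen, had 71 recovered reads in saline replicate 2 and 1887 to 4732 in the other libraries. Whether shared reads are the cause was not tested.

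Genes of B cells, plasma cells and class II antigen presentation were lower. In the B and plasma cell list 5 of 6 tested members were lower (median log2 fold change -0.71, camera adjusted p = 3.53e-04, and adjusted p = 0.659 with an estimated correlation), led by Jchain. The B cell receptor subunits Cd79b and Cd79a measured 5.72 ± 3.62 and 7.32 ± 5.17 FPKM in saline and 1.32 ± 0.166 and 1.38 ± 0.846 in Riclin (SD, n = 3 each), while saline replicate 2 held 1.56 and 1.36. Cd79b passed without that library (limma adjusted p = 0.0159, range over 16 alternatives 0.0159 to 0.965). Mzb1, of antibody-secreting cells, was 1.41-fold lower in mean FPKM, with a log2 fold change of -0.23 that was -0.011 without saline replicate 1. Class II antigen presentation genes were lower in 7 of 8 members (median -0.25, camera adjusted p = 0.0422, and adjusted p = 0.747 with an estimated correlation), with H2-Aa, H2-Eb1, H2-DMb1 and H2-DMb2 between 1.18-fold and 1.42-fold lower, and the list lost its call without any 1 of saline replicates 1 and 4 or Riclin replicates 2 and 3, where the median ranged from -0.24 to -0.093. It also lost it under median-of-ratios and upper-quartile scaling (medians -0.30 and -0.29), with pancreatic genes removed (-0.31) and with a filter at an FPKM of 5 (-0.22). The call was lost too with the pancreatic score as a covariate (-0.16), and with the replicate block or without both low-pancreas libraries (-0.088 in each). The median was -0.40 without saline replicate 2 and -0.51 without Riclin replicate 4.

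The remaining lists that passed at the preset correlation were all lower in Riclin. Antioxidant enzymes and targets of NRF2, the regulator of the antioxidant response, were lower in 21 of 31 members (median log2 fold change -0.12, camera adjusted p = 9.75e-04, and adjusted p = 0.724 with an estimated correlation). The glutathione transferases Gsta1, Gsta2 and Gstm3 were 1.82-fold, 1.47-fold and 2.38-fold lower and Srxn1 1.25-fold lower. Gsta1 was lowest in Riclin replicate 4, the library lowest in Gast, at 29.6 FPKM, and its log2 fold change of -0.94 (SE 0.284) was -0.62 without that library. The list median was -0.068 without Riclin replicate 2, -0.077 without Riclin replicate 4, -0.079 without saline replicate 1 and -0.197 without Riclin replicate 3.

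Proliferation genes were lower in 22 of 27 members (median log2 fold change -0.12, camera adjusted p = 9.69e-05, and adjusted p = 0.724 with an estimated correlation), with Mki67, Plk1, Tyms and Nusap1 1.16-fold to 1.21-fold lower. The median was -0.078 without saline replicate 4 and -0.025 without Riclin replicate 2, where the list did not pass (camera adjusted p = 0.121). Smooth muscle genes were lower in 17 of 19 (median -0.12, camera adjusted p = 1.59e-04, and adjusted p = 0.724 with an estimated correlation), with Mylk 1.25-fold, Cald1 1.23-fold, Des 1.22-fold and Synm 1.12-fold lower. That median was -0.195 without saline replicate 4 and -0.064 without saline replicate 2, where the list did not pass (0.12). Adipose genes were lower in 16 of 22 (median -0.21, camera adjusted p = 0.00458, and adjusted p = 0.784 with an estimated correlation), with Plin1, Adipoq, Fabp4 and Car3 1.42-fold to 1.58-fold lower. They did not pass without Riclin replicate 4 (median -0.021, camera adjusted p = 0.4996) or saline replicate 1 (-0.099, 0.0554), and the median was -0.39 without Riclin replicate 3. Red blood cell genes were lower in 4 of 5 (median -0.42, camera adjusted p = 0.0247, and adjusted p = 0.724 with an estimated correlation), with Hbb-bt, Alas2, Hbb-bs and Hba-a1 1.14-fold to 1.62-fold lower. They did not pass without saline replicate 2 or 4 or Riclin replicate 2 (medians -0.59, -0.41 and -0.14), with either scaling or with pancreatic genes removed, and the median was -0.93 without Riclin replicate 3 and -0.97 with the replicate block.

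In all, 17 of 43 lists passed camera at the preset correlation, 5 higher and 12 lower, and 0 passed with an estimated correlation or with fry's directional test. Among lists that did not pass were tight and adherens junctions (median 0.02, mean -0.10), mucin-type O-glycosylation (median 0.02, mean -0.06), prostaglandin synthesis and receptors (median 0.11), growth factors and epithelial repair (median -0.05) and inflammatory cytokines (median -0.01). For these junction and glycosylation lists, and for nuclear oxidative phosphorylation, liver, antimicrobial, skeletal muscle, cholesterol, fatty acid oxidation, and macrophage and dendritic cell genes, the test leaned lower while the median was positive. For mast cells it leaned higher with a negative median.

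**Figure D2:**
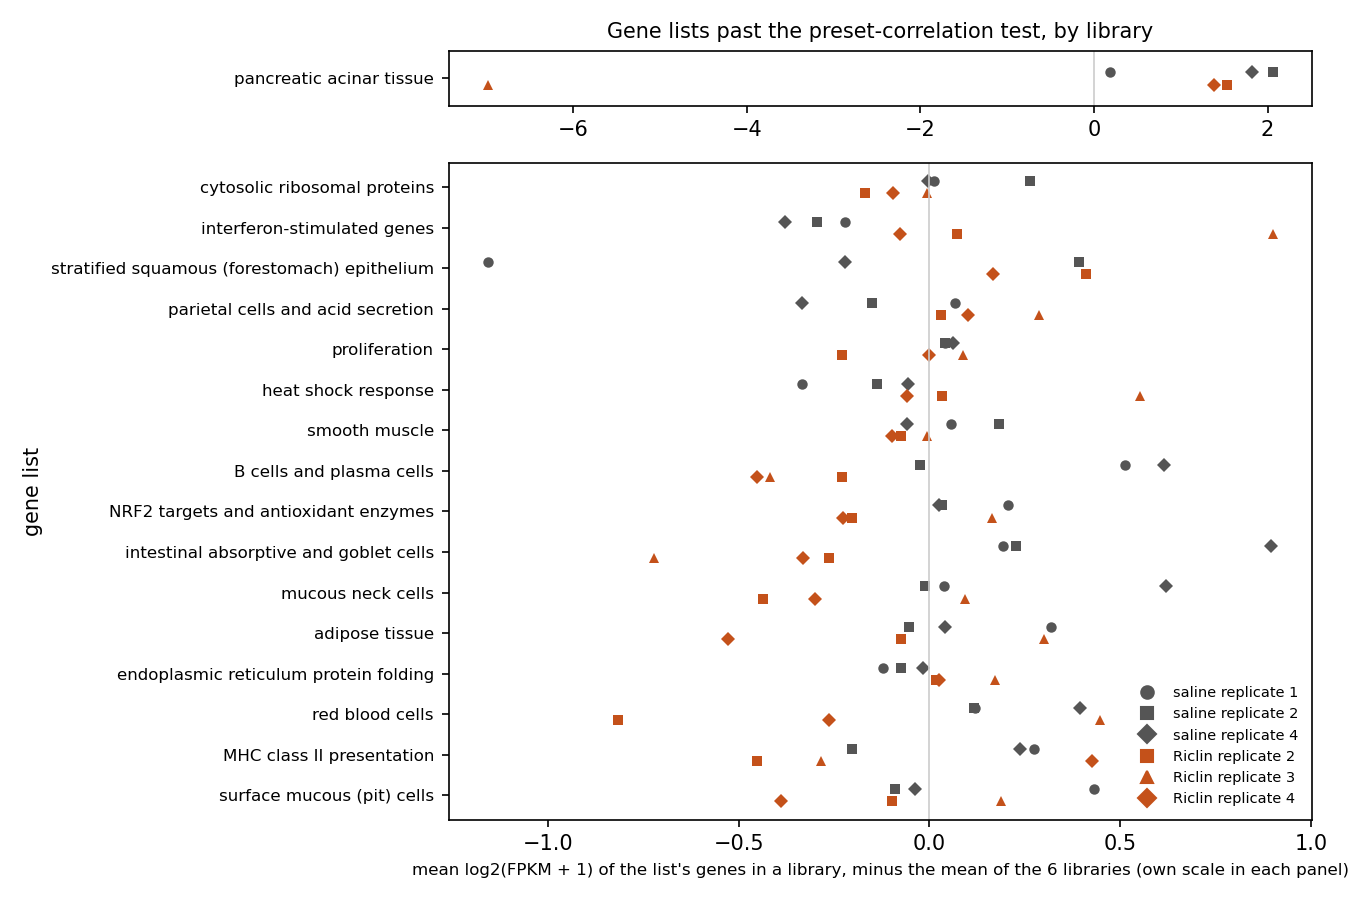
Mean log2(FPKM + 1) of each of the 17 gene lists past camera at the preset correlation, per library and relative to the mean of the 6 libraries, with grey saline and orange Riclin points and shapes for replicate numbers. The interferon-stimulated list lies at -0.22 to -0.38 in saline and at -0.08 to 0.90 in Riclin, and the acinar list lies at -6.99 in Riclin replicate 3.

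**Figure D3:**
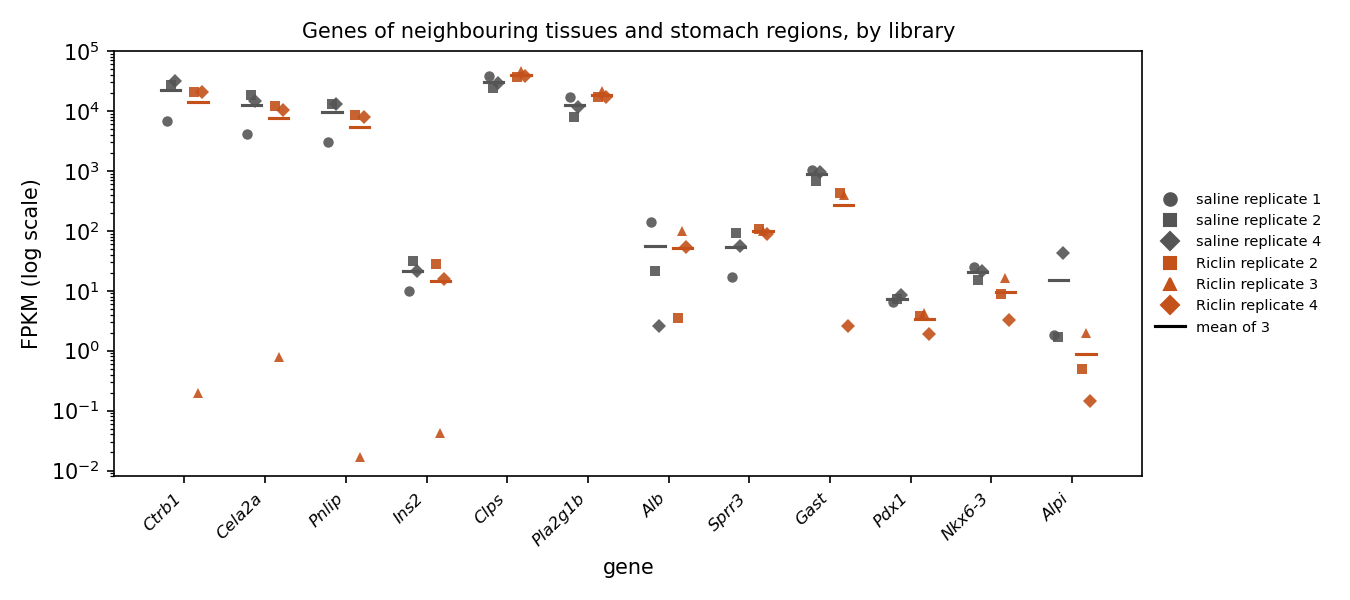
FPKM on a log scale of genes of the pancreas (Ctrb1, Cela2a, Pnlip, Ins2), of Clps and Pla2g1b, which did not follow these, and of genes of the liver (Alb), forestomach (Sprr3), antrum (Gast, Pdx1, Nkx6-3) and intestine (Alpi), chosen after values were seen, with 1 point per library and a bar for the mean of 3. Ctrb1 stands at 0.197 FPKM in Riclin replicate 3 and at 6922 to 31885 in the other libraries, while Clps stays at 23892 to 46052 in all 6. Clps and Pla2g1b are highest in Riclin replicate 3, at 46052 and 21654 FPKM, so they do not track pancreatic tissue here.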

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

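The tests on recovered reads by voom, on pancreatic transcripts and by fry were chosen after the data were seen. Genes past the limma adjusted threshold numbered 0 in the reported fit, 2 with a robust variance prior (Clca1 and Gm52608, both lower), 3 with pancreatic genes removed and libraries rescaled (Irf7 higher, Clca1 and Pcp4 lower), and 0 under the other settings except without saline replicate 2 (1, Cd79b), a range of 0 to 1 over the libraries left out in turn. The 50 genes at an unadjusted p under 0.05 and 2-fold became 91 with a pseudocount of 0.1, 28 with the robust prior, 126 with voom and 79 with the pancreatic score as a covariate, and 39 to 137 with 1 library left out, the highest without saline replicate 2 (103 higher, 34 lower). Both libraries low in pancreatic transcripts left out gave 49, and 15 lists. The 17 lists became 0 with an estimated correlation and 0 with fry's directional test (2 lists passed its test for either direction), and stayed between 13 and 19 under the other settings and between 12 and 20 with 1 library left out. The panel kept 0 genes throughout. Replicate numbers 2 and 4 occur in both groups, and deviations correlated at 0.22 and 0.01, so with 2 pairs they are not shown to pair. With the replicate block there were 0 genes, 72 at p and 2-fold (14 higher, 58 lower), 18 lists and 0 panel genes. Directions turned for Capn9 (0.026 with the replicate block and with both low-pancreas libraries left out). With 1 library left out, the log2 fold change ranged from -0.308 to 0.081 for Capn9, from -0.403 to 0.119 for Muc5ac, from -0.320 to 0.032 for Tff1 and, as the median, from -4.65 to 0.113 for the acinar list, turning without saline replicate 1 (these 3 genes), Riclin replicate 4 (Muc5ac and Tff1) or Riclin replicate 3 (the list). The acinar call was lost without Riclin replicate 3 and held with saline replicate 1 left out too (median -0.534), and the cause of the other turns and losses was not tested. Of the 90 genes of the naming rule given here, 48 had a log2 fold change that moved by over 1.5 times without some 1 library, among them Gkn1 (-0.018 without saline replicate 1), H2-DMb2 (-0.026 without saline replicate 1) and Hba-a1 (-0.034 without Riclin replicate 2). Count models on the recovered reads, planned as an alternative, were not run, and voom was the only fit on those reads. The deposited table holds FPKM, which by itself did not prevent them once whole reads were recovered. Depth differed by 1.30-fold between libraries. Genes below the FPKM filter were tested only in the fit without a filter, where 0 passed.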

Other observations

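The camera tests of lists were fixed beforehand. Limma's adjustment over a list alone was planned for the barrier panel only, and on the lists it was not corrected for the 43 lists tested. The other tests in this part were chosen or worded after the values they bear on had been seen, as were the genes named from the lists. Of the claudins, the strand-forming proteins of tight junctions, Cldn4 measured 3.15 ± 0.489 FPKM in saline and 1.53 ± 0.216 in Riclin (SD, n = 3 each), the 1 member of 27 in the junction list that passed limma adjusted over the list alone (adjusted p = 0.0156) and none over all genes. Cldn2 and Cldn7 had log2 fold changes of -1.28 and -1.04 without passing, while Cldn18, the main stomach claudin, measured 306 ± 41.9 and 308 ± 33.2 FPKM. In the glycosylation list B3galt5 alone passed over the list (limma adjusted p = 0.0463). The neutrophil alarmin S100a8 measured 0.809 ± 0.486 and 2.17 ± 0.222 FPKM and passed over its list alone (limma adjusted p = 0.0263). Its saline mean was under the filter of 1 FPKM, so it may have been tested only through its Riclin values. The neutrophil list, with 7 of 19 members tested, did not pass (camera adjusted p = 0.407). Of hormone cell genes, Chga, a general endocrine marker, measured 259 ± 6.72 and 347 ± 56.9 FPKM, and ghrelin (Ghrl) 499 ± 131 and 680 ± 128 FPKM, against the lower Gast. Fry's test for change in either direction gave an adjusted p of 0.0116 for the hormone cell list and for the intestinal absorptive and goblet cell list, the 2 lists that passed it.

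Only 4 T and NK cell genes had enough signal to be tested, too few for the list test, and all 4 were lower, with a median log2 fold change of -0.84. Ccl5, a chemokine of T cells, measured 7.88, 2.97 and 14.9 FPKM in saline and 2.62, 2.25 and 1.58 FPKM in Riclin. The 12 tested transcripts of the mitochondrial genome, not tested as a list, all had a positive log2 fold change (median 0.29), 8 of them without overlap of the groups, 1 at an unadjusted p under 0.05 and 0 past the limma adjusted threshold. All 12 stayed positive under both scalings, while ATP6, COX3 or ND4L turned when some 1 library was left out and ATP6 with the replicate block. ND1 measured 2180 ± 104 and 2814 ± 66.9 FPKM (SD, n = 3 each) and COX1 6546 ± 405 and 7416 ± 183 FPKM, and the mean was lower in Riclin for ATP6, at 16.0 ± 15.3 and 13.5 ± 1.74 FPKM, and for COX3, at 38.3 ± 17.5 and 37.9 ± 6.73 FPKM. The chitinase Chia1 of chief cells measured 4264 ± 1611 and 9875 ± 1743 FPKM, and the chief cell list missed the threshold (camera adjusted p = 0.0501). Liver albumin (Alb) varied within groups, at 143, 21 and 2.58 FPKM in saline replicates 1, 2 and 4 and at 3.45, 101 and 53.4 in Riclin replicates 2, 3 and 4.

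The interferon-stimulated genes were higher in Riclin in 32 of 36 members, 0 of them past limma over all genes, with a camera adjusted p of 1.56e-11 at the preset correlation and an adjusted p = 0.724 with an estimated correlation, and Riclin replicate 3 was highest. That library as the whole cause is argued against by the others: in 17 of the 36 members Riclin replicates 2 and 4 both exceeded all 3 saline libraries, where no other choice of 2 of these 5 libraries gave more than 5. Scaling by the pancreatic share is argued against by a median of 0.64 once those genes were removed and the libraries rescaled, though the pancreatic score as a covariate gave 0.37. More macrophages and dendritic cells would carry their own genes along, and the median of that list was 0.042 (SD over members 0.16). A response to Riclin, a difference in housing or infection between groups, differences in the piece of stomach and chance remain open. The exact two-sided permutation p of the list mean was 0.1, the smallest that 3 against 3 can give. The list also passed camera in 6 of the 9 other splits of the libraries.

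The near absence of pancreatic transcripts in Riclin replicate 3 may reflect pancreas carried over with the other stomachs and removed more cleanly there. The 5 islet genes Ins1, Ins2, Gcg, Iapp and Ppy together had 37 reads in that library and at least 484 in each of the others, so endocrine and exocrine transcripts were low together. An effect of Riclin on acinar transcripts in every treated stomach stays open: the median log2 fold change was 0.11 (SD over members 0.30) without that library and -0.53 (SD over members 0.41) with saline replicate 1, the next lowest, left out too, so it turns on a saline library.

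The antral genes Gast, of the fixed panel, and Pdx1 and Nkx6-3, picked after their values were seen, had log2 fold changes of -3.37, -0.98 and -1.24 without passing the limma adjusted threshold (adjusted p from 0.624 to 0.823), and of -1.11, -0.72 and -0.69 without Riclin replicate 4, beside the parietal list that was higher at the preset correlation (camera adjusted p = 3.68e-05, and adjusted p = 0.724 with an estimated correlation). A smaller antral part in the Riclin pieces is a candidate explanation: 16 of 17 parietal genes were higher, but the Riclin libraries did not all exceed every saline library in the parietal mean, and a loss of antral cells in the treated stomachs would look alike, so these cannot be told apart. Lower gastrin in an otherwise unchanged antrum stays open too, since Pdx1 (SE 0.222) and Nkx6-3 (SE 0.464) were picked for the pattern. So does less antrum as the cause of the lower Clca1: the mean of Gast, Pdx1 and Nkx6-3, used as a covariate, was 1.83 in Riclin replicate 4 and 4.77 to 5.88 in the other libraries (log2 scale), so it adjusts mostly for that library and decides nothing. With it the log2 fold change of Clca1 was -1.89 (SE 0.275, limma adjusted p = 0.377), the median of the interferon list 1.07, and the log2 fold changes of Fcgbp, B3galt5, Gsta1, Tff2, Gkn3, Chia1, Cblif and Atp4a -0.04, -0.70, -0.33, -0.27, -0.87, 1.29, 0.68 and 0.33.

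The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For genes past the limma adjusted threshold the real split gave 0 and the highest other 3, and a real count of 0 leaves nothing for the other splits to reach. For genes at an unadjusted p under 0.05 and 2-fold the real split gave 50 and the highest other 75, with 4 of the 10 splits at 50 or more. For gene lists the real split gave 17 and the highest other 22, with 4 of 10 at 17 or more, and for the barrier panel, where the same holds, the real split and the highest other both gave 0. Every split, real or not, called 13 to 22 lists at the preset correlation.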
